A study of Mus musculus with 6 samples.

How the data were processed

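Messenger RNA of adult mouse cerebral cortex was measured in 6 libraries, grouped by the genotype in the labels into 3 heterozygous for Setd5 and 3 wild type. Per the labels' protocols, RNA was isolated with Trizol, treated with DNase I and made into libraries from polyadenylated RNA with the TruSeq RNA Library Prep Kit v2, which does not mark the strand of a transcript. Replicate numbers follow the order of the records and were not used to pair libraries across genotypes.

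The deposited values are raw counts of reads per gene, in whole numbers and not normalized, with 1 table per library. The authors' tools, per the submitters' processing notes, were FastQC, Bowtie2 2.3.4.3, featureCounts and DESeq2, with the mouse builds mm10 and GRCm38.p6. The notes give no order or settings for these tools. Strand setting, treatment of reads that match several places, and the sequence set searched by Bowtie2 are not given in the sources used here. Bowtie2 does not by itself align a read across an intron, so if the genome was searched, reads over exon junctions would be undercounted, more so in genes with short exons. Reads of near-identical copies, of overlapping genes and of antisense pairs may be shared or lost. If all libraries were processed alike, such effects bear on levels between genes more than on differences between genotypes.

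All 55450 versioned gene identifiers matched the GENCODE M21 annotation of GRCm38, which supplied symbols, positions, exon lengths and GC content. Where a symbol had several identifiers, the one with the highest mean count was used. Every row named a gene. Totals per library ran from 82850628 to 92860628 counts, and 42216 genes had at least 1 count in some library. No pair of libraries agreed within sampling noise, with a chi-square per gene from 11.7 to 93.9 over the pairs, so none was treated as a repeat deposit.

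Genes were kept by edgeR's filterByExpr with its minimum count of 10 and minimum total of 15, which left 27939. Counts were scaled with TMM factors and tested between genotypes with glmQLFit and glmQLFTest of edgeR 4.0.16 in R 4.3.3, with no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 16.1%. Standard errors of log2 differences come from the same fit. CPM values use effective library sizes, and log2 CPM for principal components and list levels used a prior count of 1. A list level is the mean log2 CPM of the list's genes in a library, set relative to the mean of the wild type libraries. Single values were compared with two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3. A floor of 3 counts per library gives the limit that a count of 0 allows, and it covers counting error only, since reads without molecular identifiers are not independent molecules.

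Before the data were examined, 41 gene lists were fixed, of which 40 were tested and the list of X-inactivation and Y-linked genes was given per library. Of 1021 list entries 1020 matched an identifier, 8 through a newer symbol. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated from the data and with fry, whose directional p asks whether a list's genes move, on balance, one way and does not compare them with other genes. The rule for naming genes was also fixed then. It takes Setd5 first, then up to 12 genes per direction that pass the test with a mean CPM of at least 1 and groups that do not overlap, leaving out predicted models, filled to 5 by smallest p where fewer than 5 pass. Filling genes had to meet the same conditions on mean CPM, overlap of groups and predicted models. From each called list the rule takes up to 4 members by smallest p, and from each other list up to 2. Some genes that this rule takes are not reported here. Genes within 5 Mb of Setd5 were compared with the rest by Fisher's exact test.

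The test was run on simulated data drawn from the means, library sizes and dispersions of the 6 libraries, with 50 genes changed at each of 4 sizes. It recovered 44% of genes changed 1.5-fold, 52% at 2-fold, 80% at 4-fold and 96% at 8-fold, and in this single draw 156 genes were called, of which 20 were unchanged. Noise was drawn independently for each gene, without shifts shared by many genes of a library, and all 4 sizes were planted together. These shares are therefore no estimate of recovery in the real data.

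Alternatives fixed before the data were examined were other scalings (DESeq2 size factors, upper quartile, library totals), other filters on low counts (every gene with at least 1 count, or at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with and without library quality weights, robust quasi-likelihood, an adjusted p of 0.1, mitochondrial or X and Y genes left out, 1 surrogate variable from sva 3.50.0, GC and length trends removed, windows of 2 and 10 Mb, the other list tests, and each library left out in turn. Added after seeing the data were a term for the 2 libraries with high Xist counts, those libraries left out, the newer form of the quasi-likelihood fit, edgeR's likelihood ratio test, DESeq2 on every gene with at least 1 count, and the striatum level as a covariate. DESeq2 gave no adjusted p for 3260 genes, which were left out of its counts.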

Results

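Polyadenylated RNA from the adult mouse cerebral cortex was sequenced in 6 libraries, 3 from animals heterozygous for a Setd5 mutation and 3 from wild type animals. Setd5 encodes a SET-domain chromatin protein, and loss-of-function variants of the human gene are a known cause of intellectual disability and autism. The comparison asks which transcripts differ in cortex when the gene is mutated on a single copy. Gene counts summed to between 82850628 and 92860628 per library, and the totals of the groups overlapped. A count of 0 in a library allows a level of up to 0.0323 to 0.0362 CPM (the count scaled to library size), depending on the library, and this limit covers counting error only. Titles of the 6 libraries carry differing codes, but the labels do not state that the libraries of a group came from separate animals. The p-values therefore measure the spread between these libraries, which may be technical in part.

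Setd5 transcript was lower in every heterozygous library than in any wild type library. The gene (ENSMUSG00000034269.12) lies on the plus strand of chromosome 6 from 113077365 to 113153435 in GRCm38. Its level was 69.5, 68.7 and 75.3 CPM in heterozygous replicates 1 to 3, against 111, 97.0 and 108 CPM in wild type replicates 1 to 3. The group means were 71.2 ± 3.60 and 105.2 ± 7.35 CPM (SD, n = 3 each), which puts the heterozygous level at 67.7% of wild type, with a 95% interval from 60.6% to 75.6%. The log2 difference was -0.56 with a standard error (SE) of 0.07. In edgeR's quasi-likelihood test its p ranked second of the 27939 genes tested and its Benjamini-Hochberg adjusted p was 0.258, which did not pass the threshold of 0.05. The adjusted p was 3.08e-07 in DESeq2, 7.31e-05 in edgeR's likelihood ratio test and 0.0444 in limma-voom with library quality weights. Over all other fits run it ranged from 2.5e-07 to 0.9999, the highest with heterozygous replicate 1 left out. A two-sided exact permutation test of the CPM values gave p = 0.1, the smallest value that 3 libraries against 3 can give. Counts were made per gene and the labels do not say which part of the gene is altered, so transcripts of the mutant allele that still match the gene are included.

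**Figure D1:**
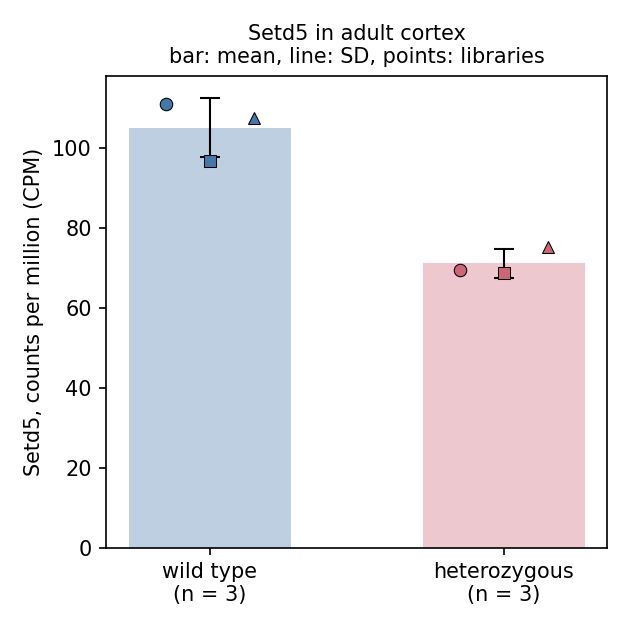
Setd5 level in CPM (y axis) in wild type and heterozygous cortex; bars are group means, lines are 1 SD (n = 3 each) and points are single libraries. The heterozygous libraries lie between 68.7 and 75.3 CPM and the wild type libraries between 97.0 and 111 CPM.

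Across the transcriptome the gene with the smallest p was Hjurp, the chaperone that loads the centromeric histone CENP-A, at 61.9 ± 0.476 CPM in heterozygous and 40.8 ± 1.68 CPM in wild type cortex (SD, n = 3 each). Its log2 difference was 0.60 (SE 0.06) and its adjusted p by edgeR was 0.0755. Glp2r, a gut hormone receptor, had a log2 difference of 0.58 (SE 0.09) and Vsig2, an immunoglobulin-domain membrane protein, one of 0.53 (SE 0.10). Spsb1, a ubiquitin ligase adaptor, differed by 0.48 (SE 0.09). Bglap3, an osteocalcin family gene, differed by 1.01 (SE 0.18) at 3.39 ± 0.461 against 1.69 ± 0.307 CPM (SD, n = 3 each). Near-identical copies lie beside Bglap3, so the assignment of its reads is uncertain. In the other direction stood Myoc, which encodes the secreted glycoprotein myocilin, at 8.76 ± 0.344 against 19.9 ± 5.19 CPM (SD, n = 3 each) and a log2 difference of -1.19 (SE 0.17). Igfbp2, a binding protein of insulin-like growth factors, differed by -0.77 (SE 0.11), the Notch ligand Jag1 by -0.86 (SE 0.14) and Chrdl1, a bone morphogenetic protein antagonist made by astrocytes, by -0.52 (SE 0.08). Ifi44, an interferon-induced gene, was at 0.486 ± 0.142 against 1.56 ± 0.172 CPM (SD, n = 3 each), a log2 difference of -1.68 (SE 0.26). Groups that do not overlap were a condition for naming these genes. None passed edgeR's test, with adjusted p from 0.0755 for Hjurp to 0.634 for Spsb1.

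In edgeR's quasi-likelihood test 0 genes were higher and 0 were lower in heterozygous cortex at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1628 genes, 683 higher and 945 lower, or 5.83% of the genes tested. The libraries of the groups did not overlap for 3278 genes, or 11.7% of those tested, where chance gives 10%. DESeq2 called 16 genes higher and 46 lower, edgeR's likelihood ratio test 13 and 16, and limma-voom 0 and 0, or 1 and 1 with quality weights. The genes called by limma-voom with quality weights were Hjurp and Setd5. With every gene that had at least 1 count in the test, edgeR called Hjurp higher and 5 genes lower, which were Myoc, Setd5, Igfbp2, Ifi44 and Ccnd1, the last named after its values were seen. Setd5 and the other genes named above passed in DESeq2, with adjusted p from 5.83e-11 for Hjurp to 0.00475 for Spsb1. Of DESeq2's 62 genes 23 were also called by the likelihood ratio test. With wild type replicate 2 left out edgeR called 2 genes, both lower. These were Myoc (log2 difference -1.39, adjusted p = 0.0032) and Ckb, the brain creatine kinase (-0.97, adjusted p = 0.0321). Ckb was named after its values were seen.

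**Figure D2:**
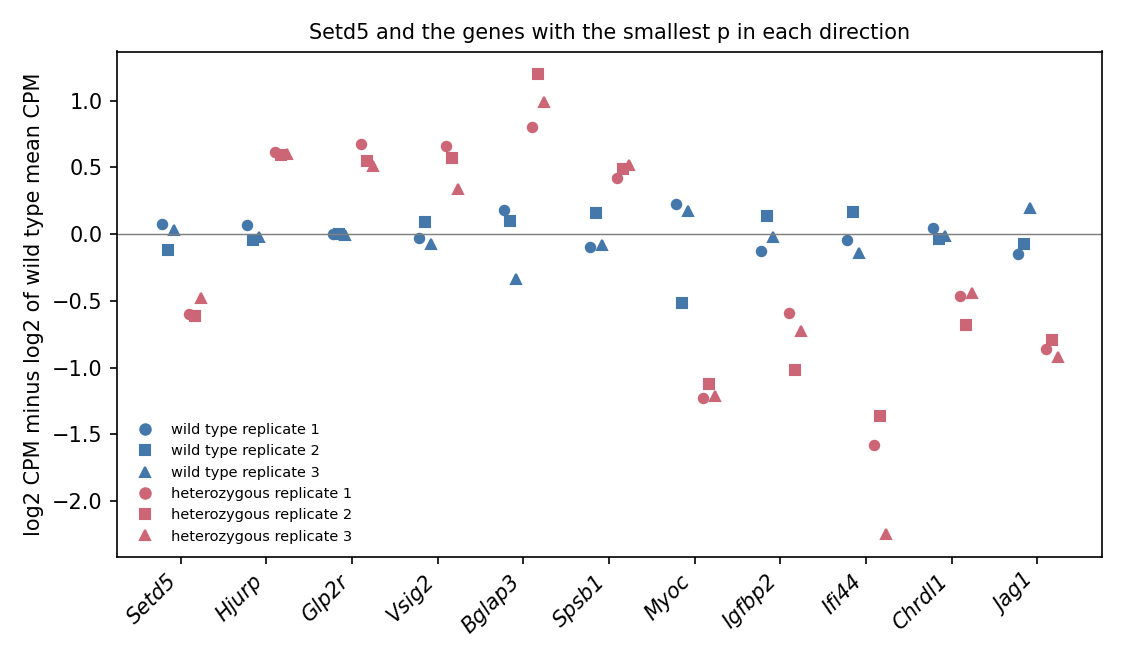
Level of Setd5 and of the genes with the smallest p in each direction, as log2 CPM of each library minus the log2 of the wild type mean CPM (y axis); points are single libraries, with colour for genotype and shape for replicate. The heterozygous points of Hjurp lie at 61.4 to 62.4 CPM and its wild type points at 39.5 to 42.7 CPM. No gene shown has overlapping groups, which was a condition for showing every gene but Setd5.

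Genes in the neighbourhood of Setd5 were examined because variants of the strain in which an allele was made can stay linked to it. Of the 139 genes tested within 5 Mb on each side, 0 were called by edgeR, and 0 by DESeq2, limma-voom or the likelihood ratio test. At an unadjusted p under 0.05 there were 3. That is 2.16% against 5.84% of the other genes tested (two-sided Fisher's exact test, p = 0.0677). Within 2 Mb it was 1 of 66 genes, or 1.52% (exact p = 0.185), and within 10 Mb 11 of 222, or 4.95% (exact p = 0.668). The 3 genes within 5 Mb were Cxcl12, a chemokine, with a log2 difference of -0.28 (SE 0.08), Mbd4, a DNA repair glycosylase, with 0.26 (SE 0.09), and Oxtr, the oxytocin receptor, with -0.45 (SE 0.17), named after their values were seen. The size of the Oxtr difference leans on wild type replicate 3, at 9.41 CPM. Wild type replicates 1 and 2 were at 6.79 and 6.56 CPM, and heterozygous replicates 1 to 3 at 6.53, 4.95 and 5.20 CPM. Gt(ROSA)26Sor, the antisense transcript used as a safe harbour locus, runs on the minus strand of chromosome 6 from 113067428 to 113077333, next to the start of Setd5. Its level was 19.5 ± 0.499 CPM in heterozygous and 19.8 ± 0.70 CPM in wild type cortex (SD, n = 3 each), with a log2 difference of -0.02 (SE 0.07), and it was also chosen after the values were seen. It overlaps Thumpd3, and the kit does not mark strand, so reads in the shared part cannot be told apart.

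Gene lists fixed before the data were examined were tested with camera on the edgeR fit. With a preset correlation between genes of 0.01, 6 of 40 lists were called higher and 11 lower at an adjusted p under 0.05. With the correlation estimated from these libraries 0 lists were called, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.378. The fry test called 0, with 6 at an unadjusted p under 0.05. In simulated counts with no genotype effect and independent noise, both called 0 of 40 lists. With 1 list shifted by 0.5 in log2 and independent noise, the preset correlation called 2 lists, 1 of them unshifted, and the estimated one only the shifted list (adjusted p = 0.0038). Where the genes of each list shared a deviation per library, with a chosen SD of 0.4 in log2, the preset correlation called 28 of 40 and the estimated one 0. That SD is near the spread of some real list levels and far above others. In heterozygous and wild type libraries it was 0.37 and 0.38 for immediate early genes, but 0.04 and 0.07 for endothelial markers. The 28 of 40 is therefore no estimate of false calls in the real data. Every direction given below for a list is the call with the preset correlation only, and none of these lists held with the estimated one. Estimated correlations of the called lists ran from -0.012 for interneuron markers to 0.797 for meningeal fibroblast markers. For interneuron markers and for axon guidance genes (-0.001) they lay under the preset 0.01. Correlation between genes therefore does not account for every lost call, and the cause was not tested.

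**Figure D3:**
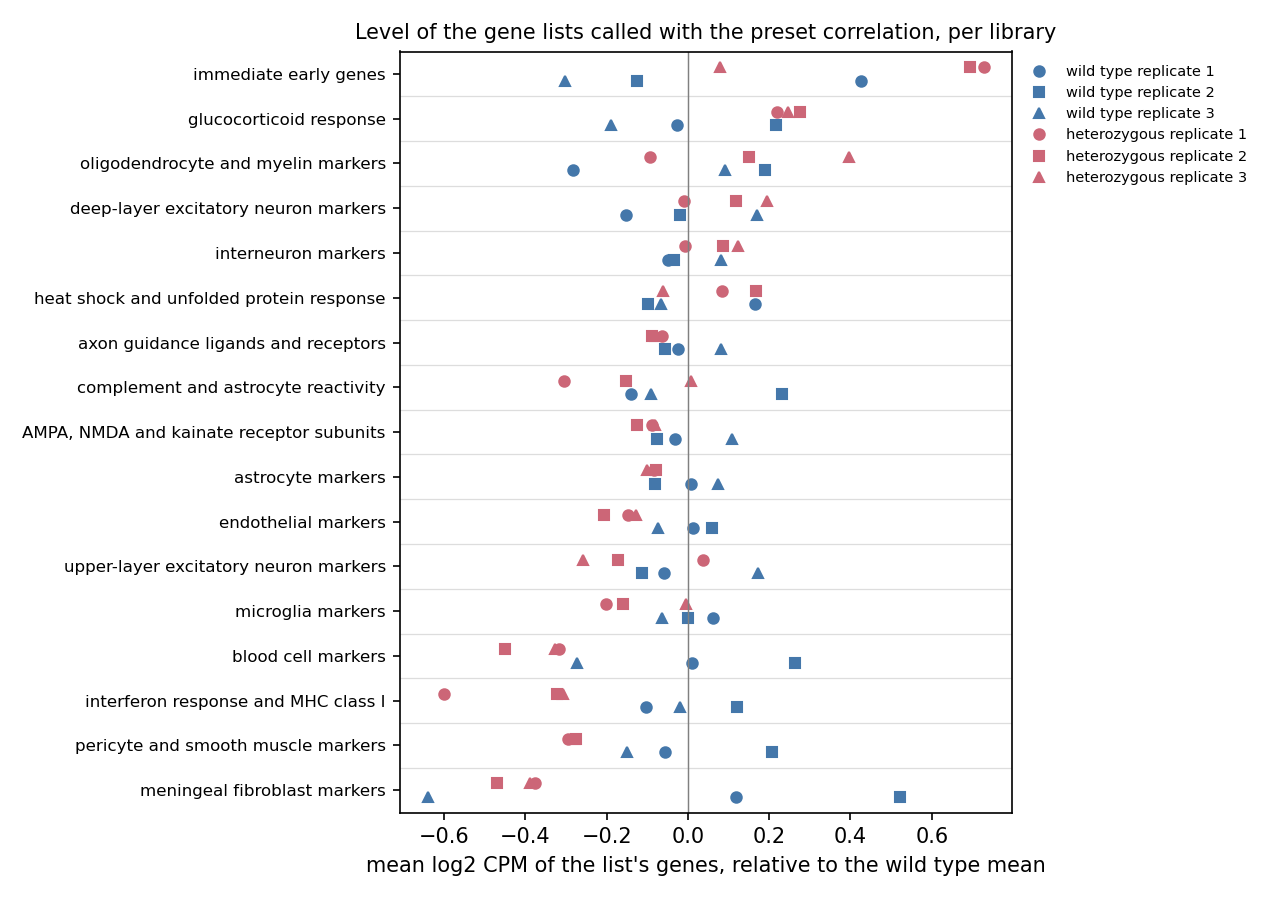
Level of each gene list called with the preset correlation, as the mean log2 CPM of its genes relative to the wild type mean (x axis), with 1 point per library, coloured by genotype and shaped by replicate. Interferon, pericyte, endothelial, blood cell, glutamate receptor and axon guidance lists have heterozygous points below all wild type points, and the glucocorticoid list above. The other lists shown have groups that overlap, the immediate early and meningeal lists among them.

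Immediate early genes, which neurons switch on within minutes of activity, were higher in heterozygous cortex. Of the 30 genes 28 had a higher fitted level and 2 a lower one, with a median log2 difference of 0.51 (camera adjusted p = 1.69e-19; adjusted p = 0.378 with an estimated correlation). Over all genes 0 members passed edgeR's test, 12 stood at an unadjusted p under 0.05, and 1 passed when adjusted over the list alone. That gene was Nptx2, a secreted pentraxin of excitatory synapses, at 70.9 ± 13.3 against 46.1 ± 2.68 CPM (SD, n = 3 each), and it was also called by DESeq2 (adjusted p = 0.0018). Npas4, an activity-dependent transcription factor, was at 17.8 ± 4.83 against 10.3 ± 2.63 CPM (SD, n = 3 each). Egr3 was at 155 ± 47.4 against 103 ± 11.1 CPM and Ier5 at 110 ± 23.6 against 81.2 ± 5.44 CPM. The list's level per library, in log2 relative to the wild type mean, was 0.73, 0.69 and 0.08 in heterozygous replicates 1 to 3 and 0.43, -0.12 and -0.30 in wild type replicates 1 to 3, so the groups overlapped.

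Glucocorticoid-responsive genes were also higher, with 14 of 15 members above wild type and a median log2 difference of 0.26 (camera adjusted p = 1e-07; adjusted p = 0.378 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 7 passed in the higher direction and 1 in the lower. Fkbp5, a chaperone of the glucocorticoid receptor, was at 33.1 ± 0.422 against 24.6 ± 4.03 CPM (SD, n = 3 each). Ddit4, an inhibitor of mTOR signalling, was at 44.7 ± 3.33 against 37.2 ± 3.25 CPM. Cdkn1a, a cell cycle inhibitor, had a log2 difference of 0.57 (SE 0.17). Pdk4, a kinase that restrains pyruvate oxidation, was the member on the other side, with -0.48 (SE 0.13). The list shares 1 gene with the immediate early list. Heat shock and unfolded protein response genes had a median of 0.08 with 18 of 20 members above wild type (camera adjusted p = 0.0371; adjusted p = 0.792 with an estimated correlation), among them Atf4 at 0.15 (SE 0.07) and Ddit3 at 0.20 (SE 0.09). Adjusted over the list alone 0 passed, with 1 at an unadjusted p under 0.05. This call ended on leaving out heterozygous replicate 1 (median 0.05) or 2 (0.05), or wild type replicate 2 (0.06) or 3 (0.04). The median was 0.16 without heterozygous replicate 3 and 0.14 without wild type replicate 1. The heat shock call also ended in limma-voom with quality weights (0.06), with 1 surrogate variable (0.05), with the length trend removed (0.09) and with the striatum level as a covariate (0.06). Ddit3 was at 0.12 without heterozygous replicate 2.

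Genes of the interferon response and of antigen presentation by major histocompatibility complex (MHC) class I were lower in heterozygous cortex. Of 24 members 23 lay below wild type, with a median log2 difference of -0.31 (camera adjusted p = 5.66e-10; adjusted p = 0.378 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 6 passed in the lower direction and 1 in the higher. Besides Ifi44, these included Tap1, a peptide transporter for MHC class I loading, at 0.93 ± 0.162 against 1.60 ± 0.331 CPM (SD, n = 3 each). Oas1a, an antiviral nucleotide synthase with close paralogs and few counts, was at 0.0571 ± 0.0215 against 0.183 ± 0.028 CPM. Ifit2 was the member on the higher side, at 23.3 ± 0.765 against 19.2 ± 1.58 CPM (SD, n = 3 each). The level of the list was lower in each heterozygous library, between -0.60 and -0.31, than in any wild type library, between -0.10 and 0.12. A two-sided exact permutation test of these levels gave p = 0.1, the smallest that 3 against 3 can give. The glucocorticoid, pericyte, endothelial, blood cell, glutamate receptor, axon guidance and uncalled non-clustered cadherin lists also had groups that did not overlap. For a single list chance gives such a separation in 10% of cases.

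Markers of cells of the vessel wall and the brain coverings were lower as well. Among 18 meningeal fibroblast markers 16 lay below wild type, with a median log2 difference of -0.57 (camera adjusted p = 1.66e-09; adjusted p = 0.468 with an estimated correlation). Col1a1, a fibrillar collagen chain, was at 5.12 ± 1.13 against 9.38 ± 3.33 CPM (SD, n = 3 each) and the transporter Slc6a13 at 5.47 ± 0.284 against 8.10 ± 2.12 CPM. The organic anion transporter Slc22a6 was at 3.93 ± 0.427 against 6.23 ± 1.83 CPM and the proteoglycan Dcn at 12.7 ± 1.05 against 22.1 ± 9.92 CPM. Adjusted over the list alone 0 meningeal genes passed, with 8 at an unadjusted p under 0.05, and DESeq2 called Col1a1 (adjusted p = 0.0399). The log2 difference of Col1a1 went from -0.87 to -0.57 without wild type replicate 1, and without wild type replicate 2 that of Slc6a13 went from -0.57 to -0.35 and that of Dcn from -0.79 to -0.41. Meningeal levels ran from -0.64 to 0.52 within the wild type group and from -0.47 to -0.38 in the heterozygous group. The median was -0.29 without wild type replicate 2. Pericyte and smooth muscle markers had a median of -0.38 with 13 of 16 below wild type (camera adjusted p = 1.48e-06; adjusted p = 0.378 with an estimated correlation), and a median of -0.14 without wild type replicate 2. Adjusted over the list alone 3 passed, all lower. Vtn, the matrix protein vitronectin, was at 37.2 ± 1.05 against 50.6 ± 6.87 CPM (SD, n = 3 each). The potassium channel subunit Abcc9 had a log2 difference of -0.41 (SE 0.12) and the growth factor receptor Pdgfrb one of -0.35 (SE 0.11). Endothelial markers had a median of -0.12 with 19 of 22 below wild type (camera adjusted p = 2.14e-05; adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone 0 endothelial genes passed, with 7 at an unadjusted p under 0.05, such as the adhesion molecules Pecam1 at -0.37 (SE 0.10) and Cdh5 at -0.42 (SE 0.12). The endothelial median was -0.19 without heterozygous replicate 3 and -0.20 without the 2 libraries with high Xist counts.

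Blood cell markers had a median of -0.30 with 9 of 13 below wild type (camera adjusted p = 0.0041; adjusted p = 0.378 with an estimated correlation). Adjusted over the list alone 0 passed, with 3 at an unadjusted p under 0.05. The haemoglobin gene Hbb-bs, whose reads are shared with a near-identical neighbour, was at 16.3 ± 0.562 against 20.1 ± 2.03 CPM (SD, n = 3 each), and the MHC class II gene H2-Ab1 at 0.335 ± 0.0113 against 1.01 ± 0.76 CPM. The log2 difference of H2-Ab1 was -1.59, and -0.78 without wild type replicate 2. Haemoglobin genes took 0.00207% of counts in the heterozygous and 0.0025% in the wild type group (two-sided exact permutation p = 0.1). The call on the blood list ended without heterozygous replicate 3 (median -0.30) or wild type replicate 2 (-0.25) and under a filter of at least 1 CPM in 3 libraries (-0.25), and without wild type replicate 1 the median was -0.14.

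Microglia markers had a median of -0.14 with 21 of 22 below wild type (camera adjusted p = 0.000228; adjusted p = 0.468 with an estimated correlation). The complement gene C1qa was at 32.8 ± 3.11 against 38.0 ± 1.16 CPM (SD, n = 3 each) and Tmem119 at 19.0 ± 0.585 against 22.1 ± 2.02 CPM. The microglia median was -0.08 without heterozygous replicate 2, -0.09 without wild type replicate 1 and -0.23 without both libraries with high Xist counts. Astrocyte markers had a median of -0.11 with 16 of 20 below wild type (camera adjusted p = 0.0011; adjusted p = 0.388 with an estimated correlation), such as the water channel Aqp4 at -0.28 (SE 0.08) and the gap junction gene Gja1 at -0.20 (SE 0.07). The astrocyte call ended without wild type replicate 3 (median -0.11) and without both libraries with high Xist counts (-0.08). Complement and astrocyte reactivity genes, which share 3 genes with the microglia list, had a median of -0.08 with 14 of 18 below wild type (camera adjusted p = 0.0356; adjusted p = 0.468 with an estimated correlation), with Serping1 at -0.71 (SE 0.30), or -0.23 without wild type replicate 2. This call ended without heterozygous replicate 1 (median -0.05) or 2 (-0.09), and without wild type replicate 2 the median was 0.03. The complement median was -0.27 without heterozygous replicate 3, -0.24 without wild type replicate 1 and -0.15 without wild type replicate 3. It was -0.17 in limma-voom with quality weights, -0.13 with a term for the libraries with high Xist counts and -0.33 without them. Oligodendrocyte and myelin markers were on the higher side, with a median of 0.16 and 19 of 24 above wild type (camera adjusted p = 0.000509; adjusted p = 0.737 with an estimated correlation). Mbp, myelin basic protein, was at 4462 ± 1075 against 3397 ± 546 CPM (SD, n = 3 each), and its log2 difference of 0.39 was 0.19 without heterozygous replicate 3. The oligodendrocyte call ended without heterozygous replicate 3 (median 0.05) or wild type replicate 1 (0.06), and without both libraries with high Xist counts (0.04). The median was 0.26 without heterozygous replicate 1. Adjusted over each list alone 0 microglia, astrocyte, complement or oligodendrocyte genes passed, with 2, 5, 2 and 2 at an unadjusted p under 0.05.

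Among neuronal lists, upper-layer excitatory markers had a median of -0.14 with 9 of 14 below wild type (camera adjusted p = 0.0344; adjusted p = 0.587 with an estimated correlation). The calcium binding protein Calb1 had a log2 difference of -0.25 (SE 0.10) and the layer-defining receptor Rorb one of -0.31 (SE 0.13). Without heterozygous replicate 1 these were -0.39 and -0.49, and Rorb was at -0.19 without heterozygous replicate 2. Deep-layer markers had a median of 0.11 with 13 of 20 above wild type (camera adjusted p = 0.0459; adjusted p = 0.587 with an estimated correlation). Fezf2, a regulator of subcerebral projection neurons, was at 31.9 ± 2.62 against 23.4 ± 6.35 CPM (SD, n = 3 each), and its log2 difference of 0.45 was 0.24 without wild type replicate 3. Interneuron markers had a median of 0.11 with 16 of 26 above wild type (camera adjusted p = 0.0356; adjusted p = 0.378 with an estimated correlation). The neuropeptide Cort was at 7.15 ± 0.866 against 4.82 ± 0.827 CPM (SD, n = 3 each) and, on the lower side, Reln at 42.5 ± 2.58 against 48.6 ± 1.71 CPM. Glutamate receptor subunits of the AMPA, NMDA and kainate classes had a median of -0.10 with 14 of 18 below wild type (camera adjusted p = 0.0178; adjusted p = 0.468 with an estimated correlation), such as Grin2c at -0.35 (SE 0.12), or -0.18 without wild type replicate 3. Axon guidance ligands and receptors had a median of -0.07 with 27 of 43 below wild type (camera adjusted p = 0.0178; adjusted p = 0.378 with an estimated correlation). The ephrin receptor Epha3, at 8.72 ± 0.674 against 13.1 ± 2.00 CPM (SD, n = 3 each), was the 1 member that passed when adjusted over the list alone, and DESeq2 called it too (adjusted p = 0.0092). In the other lists of this paragraph 0 members passed when adjusted over the list alone, with 2 upper-layer, 3 deep-layer, 3 interneuron and 1 glutamate receptor gene at an unadjusted p under 0.05. Without wild type replicate 3 the calls ended for upper-layer markers (median -0.02), glutamate receptors (-0.02) and axon guidance genes (-0.03). Without heterozygous replicate 2 they ended for upper-layer (-0.16), deep-layer (0.09), interneuron (0.08) and glutamate receptor genes (-0.08). Without heterozygous replicate 3 they ended for upper-layer (-0.09), deep-layer (0.06), interneuron (0.09) and axon guidance genes (-0.07). Without wild type replicate 1 they ended for deep-layer (-0.01) and interneuron genes (0.10), and without wild type replicate 2 for interneuron genes (0.11). The upper-layer median was -0.21 without heterozygous replicate 1. Removal of the length trend ended the upper-layer (-0.13), glutamate receptor (-0.08) and axon guidance calls (-0.06), and so did leaving out both libraries with high Xist counts (0.01, -0.04 and -0.04). The upper-layer call also ended in limma-voom with quality weights (-0.08), the interneuron call without X and Y genes (0.10), and the deep-layer call in DESeq2 (0.11) and under a filter of at least 1 CPM in 3 libraries (0.11). The deep-layer median was 0.05 without both libraries with high Xist counts, and the axon guidance median -0.04 with 1 surrogate variable.

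The other 23 lists were not called, with camera adjusted p of 0.0528 or more. Synaptic and adhesion lists had medians of -0.06 for non-clustered cadherins and protocadherins, -0.03 for GABA and glycine receptor subunits, -0.05 for postsynaptic scaffolds, 0.01 for presynaptic vesicle release, -0.09 for metabotropic glutamate receptors and -0.003 for voltage-gated channels. Gabrb1, a subunit of the GABA-A receptor, at 168.5 ± 3.27 against 199 ± 5.73 CPM (SD, n = 3 each), was the 1 receptor gene of its list that passed when adjusted over the list alone. Shank3, a postsynaptic scaffold gene linked to autism, was at 127 ± 9.76 against 159.7 ± 18.3 CPM (SD, n = 3 each) and did not pass. Genes linked to autism and intellectual disability had a median of -0.005, with 21 of 45 above and 24 below wild type (camera adjusted p = 0.727). Histone methyltransferases had one of 0.04 (adjusted p = 0.475) and the NCoR-HDAC3 and PAF1 complexes, which bind Setd5 protein, one of -0.01 (adjusted p = 0.804). Lists of growth and metabolism had medians of 0.02 for cytosolic ribosomal proteins, 0.04 for ribosome biogenesis, 0.01 for nuclear-encoded oxidative phosphorylation, -0.05 for mitochondrially encoded genes, 0.05 for cholesterol synthesis, -0.03 for hypoxia and 0.04 for the circadian clock. Oligodendrocyte precursor markers had a median of -0.05, with Pdgfra at 60.2 ± 6.45 against 71.9 ± 3.19 CPM (SD, n = 3 each). Choroid plexus and ependymal markers had one of 0.01, with the ciliary gene Tmem212 at 1.54 (SE 0.33) and Kl at -0.91 (SE 0.23), which both passed when adjusted over the list alone. Markers of hippocampus had a median of -0.02, with Trpc6 at -0.55 (SE 0.13) as the 1 gene passing when adjusted over the list alone. Markers of thalamus, hypothalamus and midbrain had a median of 0.03, clustered protocadherins, whose shared exons leave single members uncertain, one of -0.05, and polyadenylated histone genes one of -0.02. For these last 3 lists and for hippocampus the median, the mean and the test differed in sign.

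Striatum markers differed between libraries more than between genotypes. Their median log2 difference was -0.60, and 19 of 20 lay below wild type (camera adjusted p = 0.0528; adjusted p = 0.86 with an estimated correlation). The list's levels were -1.54, -0.21 and 0.69 in heterozygous replicates 1 to 3 and -1.55, -0.25 and 1.80 in wild type replicates 1 to 3. The lower mean level in heterozygous cortex thus rests on wild type replicate 3 alone. The dopamine receptor gene Drd2 was at 0.435, 3.26 and 9.82 CPM in heterozygous replicates 1 to 3 and at 0.603, 4.27 and 30.8 CPM in wild type replicates 1 to 3. The adenosine receptor gene Adora2a ranged from 1.48 to 59.5 CPM over the 6 libraries. The first principal component of log2 CPM held 29.4% of the variance and set wild type replicate 3, at 71.4, apart from the others, at -22.8 to 7.48. Xist, the transcript of the inactive X chromosome, was at 865 CPM in heterozygous replicate 3 and 784 CPM in wild type replicate 3 and between 0.45 and 0.876 CPM in the other 4 libraries. The Y-linked gene Ddx3y was at 1.65 and 1.77 CPM in the libraries with high Xist and between 96.5 and 106 CPM in the others. Each genotype held 1 library of the first kind and 2 of the second, so its libraries did not all come from a single animal. With a model term for these libraries, or with both left out, edgeR called 0 genes, with 2030 and 2211 at an unadjusted p under 0.05, and with the striatum level as a covariate it called 0, with 1749. Mitochondrial transcripts took 7.47% to 9.58% of counts per library and the 10 most counted genes 8.84% to 11.6%. Cytosolic ribosomal protein genes, which share reads with many pseudogenes, took 0.115% to 0.123%.

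**Figure D4:**
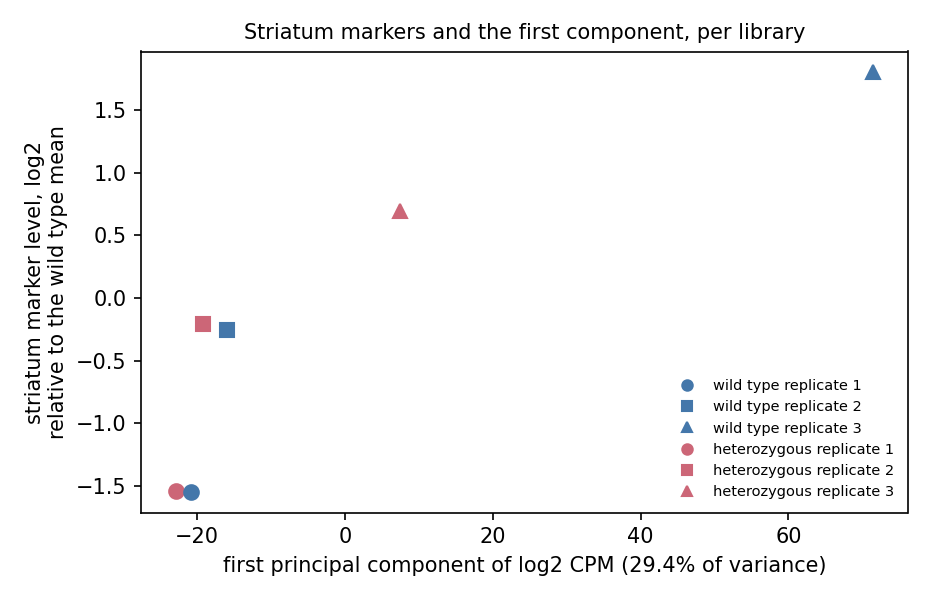
Striatum marker level, as mean log2 CPM relative to the wild type mean (y axis), against the first principal component of log2 CPM (x axis), with 1 point per library. Wild type replicate 3 lies at a level of 1.80 and a component value of 71.4, and the other libraries at levels from -1.55 to 0.69.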

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

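Tests chosen only after the result was seen were the likelihood ratio test, the newer quasi-likelihood form, DESeq2 on every gene with at least 1 count, the term for the 2 libraries with high Xist counts, leaving those out, and the striatum covariate. Setd5 had a negative log2 difference in all 27 other fits, from -0.62 to -0.52. It passed with every gene that had at least 1 count (-0.57), in DESeq2 (-0.57), in limma-voom with quality weights (-0.59), in the likelihood ratio test (-0.56) and in DESeq2 on every gene with at least 1 count (-0.57). Genes called were 0 higher and 0 lower by edgeR's quasi-likelihood test (1628 at an unadjusted p under 0.05), 1 and 5 with every gene that had at least 1 count, 16 and 46 in DESeq2, 1 and 1 in limma-voom with quality weights, 13 and 16 in the likelihood ratio test, 14 and 45 in DESeq2 on every gene with at least 1 count, 1 higher with robust estimation and 1 higher at an adjusted p of 0.1. With 1 library left out the count of genes lower ranged from 0 to 2, the 2 without wild type replicate 2, and that of genes higher was 0. The cause of these moves was not tested. Lists called went from 6 higher and 11 lower to 0 and 0 with an estimated correlation and to 0 and 0 in fry, and the lists higher ranged from 3 to 7 with 1 library left out. The immediate early, glucocorticoid, interferon, meningeal, pericyte, endothelial and microglia lists were called with the preset correlation in all 27 other fits, and the other 10 called lists were lost in some. The median reversed for deep-layer markers (-0.0075 without wild type replicate 1, in a range up to 0.13 with 1 library left out), for complement genes (0.034 without wild type replicate 2, in a range down to -0.27) and for upper-layer markers (0.0127 without both libraries with high Xist counts), and the Cd74 log2 fold change reversed to 0.0338 without wild type replicate 2, in a range down to -1.12 with 1 library left out. The cause was not tested. The counts near Setd5 stayed at 0 in every fit and window. With 3 libraries a group, simulated changes of 1.5-fold were recovered in 44% of genes. The simulated noise was independent between genes and changes of up to 8-fold were planted beside them. The 44% is therefore no estimate of the share recovered in the real data. No paired fit was run, since the labels share no replicate number between the genotypes and the numbers used here only follow the order of the records.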

Other observations

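Tests chosen only after the result was seen were the count of DESeq2 calls over the other splits of the libraries and the fit with the striatum level as a covariate, and the genes of the next paragraph were chosen after their values were seen. The other checks below address patterns already seen in these data. They were not part of the tests fixed before the data were examined.

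DESeq2 called 46 genes lower in heterozygous cortex, and a few outside the fixed lists are given here as values, with no test of them as a group. The guanylate-binding protein genes Gbp4, at 0.693 ± 0.158 against 2.11 ± 1.06 CPM (SD, n = 3 each), and Gbp9, at 3.79 ± 0.258 against 5.69 ± 0.435 CPM, overlap on chromosome 5, so their reads cannot be fully told apart. The interferon-inducible GTPase genes Igtp, at 3.35 ± 0.227 against 6.08 ± 2.04 CPM, and Ifi47, at 0.627 ± 0.0639 against 1.72 ± 0.964 CPM, lie apart on chromosome 11. Ccnd1, which encodes a cyclin of the G1 phase, was at 20.0 ± 3.61 against 37.9 ± 8.89 CPM and the leptin receptor gene Lepr at 4.42 ± 0.614 against 7.29 ± 0.393 CPM (SD, n = 3 each). Ccnd1 had an adjusted p of 6.2e-05 in DESeq2 and 0.634 in edgeR's quasi-likelihood test, and the 62 genes had edgeR adjusted p from 0.0755 to 0.789.

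Immediate early genes were higher in heterozygous cortex by a mean log2 level of 0.50. A single library as the source is argued against, since the difference was at least 0.349 whichever library was left out. Time of day of collection may contribute: the phase of clock genes differed by 0.0372 between genotypes, but its 95% interval ran from -0.70 to 0.77, so this stays open. Of the 10 splits of the libraries into 3 and 3, 2 gave a level difference as large, the real one included, the highest other being 0.73, and 10 splits are too few for a share under 0.05. Genotype stays among the open explanations, and handling of the animals before collection was not tested.

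Meningeal, vascular and interferon genes each had a lower mean level in heterozygous cortex, but did not move together in every library. Wild type replicate 3 had the lowest meningeal level of all libraries, at -0.64. Its interferon level of -0.02 and endothelial and mural level of -0.11 lay above every heterozygous library. If meningeal tissue left on the dissected cortex were the whole source, no difference in endothelial and mural genes should remain at an equal meningeal level. These genes did follow the meningeal level in wild type libraries. After the slope within genotypes was removed, -0.1351 of the original -0.21 remained, or 63.6%, with a 95% interval from -0.23 to -0.05. The slope rests mostly on the wild type libraries, since heterozygous meningeal levels ran only from -0.47 to -0.38. Among them wild type replicate 3 lay farthest from its group mean, at a meningeal level of -0.64 and an endothelial and mural level of -0.11. That library also lay apart on the first principal component. No fit without it was run, so the remainder cannot decide. Meningeal tissue stays open as the whole source for these genes. For interferon genes -0.3783 of the original -0.41 remained, or 92.2%. The 95% interval of this remainder ran from -0.86 to 0.10, so meningeal tissue cannot be told apart from genotype there with 6 libraries. A single library is open for the meningeal genes, since their difference of -0.41 became -0.1507 without wild type replicate 2 and -0.73 without wild type replicate 3, and 4 of 10 splits gave one as large, the real one included, the highest other being 0.59, with 10 splits too few for a share under 0.05. Genotype remains an open explanation for the interferon, endothelial and mural genes.

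Wild type replicate 3 lay apart on the first principal component, by 67.8% of the component's range from the nearest library. Sex chromosome genes as the source are argued against, since without X and Y genes the gap was 82.8%. Striatal tissue taken along in the dissection is a candidate explanation, since the level of 20 striatum markers in this library lay 1.105 above the highest of the other libraries, with Drd2 at 30.8 CPM. The label of this library is written in another pattern than those of the other 5, and no label states a batch, so whether it was collected or sequenced apart is open and was not tested. Beyond the sex chromosome genes and the striatum markers no explanation was tested for this library. Adding the striatum level to the model left 0 genes called by edgeR, with 1749 at an unadjusted p under 0.05.

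With 3 libraries against 3 there are 10 splits, too few for a share under 0.05 in any count. For genes at an unadjusted p under 0.05 in edgeR the real split gave 1628 and the highest other 1804, with 4 splits as large, and here and below such a number of splits includes the real one. For lists called with the preset correlation it gave 17 against 19, with 3 as large, and for genes called by DESeq2 62 against 111, with 2 as large.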
